A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

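Poly(A) RNA was measured by sequencing in 6 libraries of the budding yeast Saccharomyces cerevisiae, of W303, a laboratory strain. The libraries fall into 3 groups, T1, T2 and T3, with 2 libraries each, replicates A and B. Per the labels' protocols, mRNA was enriched with oligo(dT), libraries were made with an NEBNext Ultra RNA kit, and paired reads of 150 bases were read on a NovaSeq. Per the submitters' processing notes, the tools were STAR 2.5.2b, featureCounts and Subread 1.5.2, with genome build R64; what each was run with is not recorded. Without a recorded strand setting, reads of a gene and of a transcript on the opposite strand cannot be told apart. The handling of reads that match several near-identical genes is not recorded either. The deposited values are TPM, a relative abundance corrected for gene length, per the file headers and name, and each library's values add up to the same total.

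The table held 6401 entries, of which 1 had no gene name. The unnamed entry held 4.74 to 5.83 TPM and was left out. Of the 6400 named entries, 6162 were matched to the SGD R64-5-1 annotation, 6127 by symbol or locus tag and 35 by synonym. Of the 238 unmatched names, 228 have the form of a tRNA or snoRNA name and 2 look like dates. Matched entries include 5968 protein-coding genes. The list of mitochondrial-genome mRNAs has 0 members in the table and was not analysed here. Genome coordinates are those of R64.

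TPM values carry no depth of their own. Multiplying each value by the annotated exonic length gave numbers proportional to fragments, and the factor that makes them whole was found for each library. With it, 99.84 to 99.93% of the open reading frames with at most 500 fragments lay within 0.1 of a whole number. Recovered totals were 22497344 and 22111784 fragments on genes in T1 replicates A and B, 19107725 and 20076844 in T2, and 17881463 and 23549197 in T3. The median open reading frame held 1104 to 1468 fragments per library. Counting error was therefore small for most genes, and PCR copies cannot be removed from these totals.

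The comparisons were T3 against T1 (the main comparison), T2 against T1, T3 against T2, any difference among the groups, and the difference between the T2 to T3 step and the T1 to T2 step. Values were transformed as log2(TPM + 1) for the 6046 genes with a mean of at least 1 TPM. All 6 libraries entered 1 fit of group means in limma 3.58.1 (R 4.3.3), with lmFit, contrasts.fit and eBayes with an abundance trend, which had 3 residual and 10.7 prior degrees of freedom. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Log2 changes and folds are on the log2(TPM + 1) scale, which makes the folds of genes at a few TPM smaller than the ratios of their TPM. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

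A set of 35 gene lists was fixed before the data were examined, and 34 of them had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves 1 way on balance, stand beside it. With an estimated correlation, camera rests on the 3 residual degrees of freedom, which leaves it little power. A list that misses the threshold there is not thereby shown to be unmoved. Where the estimated correlation of a list lies above 0.01, its p-value at the preset correlation may be too small. The comparisons, tests, named-gene rule and alternatives were also chosen before the data were examined, apart from those said to have been added. The rule took, among genes past the threshold whose libraries did not overlap and with a mean of at least 10 TPM in a group, the 8 largest rises and 8 largest falls in T3 against T1 and the 5 largest of each in the other pairs of groups. It also took the most abundant member of each list with its 2 largest rises and 2 largest falls, a set of genes by name, and the 4 largest differences of each sign between the steps. The genes taken by name were CLN1, CLN2, CLN3, WHI5, SWI4, SIC1, CLB2, RPO21, HSP12, CTT1, MSN2, MSN4, GCN4, SFP1, ACT1, TDH3 and PMA1.

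The gene test was checked on simulated data with 50 genes changed at each fold size among 6046. The changed genes were drawn from those at about 10 TPM or more, so recovery at lower abundance was not checked. The noise was normal with limma's own estimates of spread, so departures from the model were not checked either. For T3 against T1, 94% of the genes changed 1.5-fold and 100% of those changed 2-fold, 3-fold and 4-fold were recovered, and 12 unchanged genes were called. For T3 against T2, 100% were recovered at each of these sizes and 15 unchanged genes were called. A simulated list of 135 moved genes was called by camera in T3 against T1, with 0 unmoved lists called. The simulated genes varied independently, while estimated correlations within the tested lists reached 0.791 in the data. These simulations therefore do not check false calls of lists whose members vary together.

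Alternatives were other pseudocounts, other abundance filters, rescaling by the median of ratios, quantile normalization, protein-coding genes alone, no abundance trend, a block for the replicate letter, each library left out in turn, a minimum log2 change of 1, and the other list tests. After the data were seen, limma voom on the recovered fragments, removal of the trend with gene length, and genes of at least 500 nt alone were added. The cut at 500 nt drops shorter members from the gene lists, so a list's call there is of its longer members alone. Overlaps between comparisons that share libraries were set against 100 simulated data sets with unchanged groups and independently drawn genes.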

Results

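The data are TPM values of poly(A) RNA from 6 libraries of budding yeast, 2 in each of the groups T1, T2 and T3. The titles mark all 6 as arrest samples, and the series' design names cultures of 3 mean cell sizes. The labels give neither a size nor a time for any group, nor how the cells were arrested, so the groups are compared by name. Recovered depths were 22497344 and 22111784 fragments for T1 replicates A and B, 19107725 and 20076844 for T2, and 17881463 and 23549197 for T3. At these depths 5869 to 5880 open reading frames had a value above 0. Across genes, the Spearman correlation of the replicates' TPM was 0.9939 in T1, 0.9963 in T2 and 0.9956 in T3. Replicates still differed by more than counting error. On average over genes, squared differences of recovered fragments were 18.54, 11.57 and 14.47 times those of counting error in T1, T2 and T3. The leading component of the values held 70.8% of the variance and placed the T1 libraries at 0.499 and 0.503, the T2 libraries at 0.016 and -0.02, and the T3 libraries at -0.524 and -0.473. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values may measure technical spread alone.

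T3 was compared with T1 to ask how transcript abundance differed between the outermost groups. In T3, 51 of 62 general stress genes rose and 3 fell (median 2.09-fold over all 62), and 18 of 21 trehalose and glycogen genes, all 16 genes of the tricarboxylic acid cycle and 35 of 36 nuclear genes of oxidative phosphorylation rose. Each of these lists passed camera, and had an adjusted p = 0.425 with an estimated correlation, a test with little power at 3 residual degrees of freedom. Of 135 ribosome biogenesis genes 97 fell and 0 rose, of 138 cytosolic ribosomal protein genes 91 fell and 3 rose, and of 24 heat shock chaperone genes 19 fell and 1 rose. These lists passed camera too, and each had an adjusted p = 0.425 with an estimated correlation. For the lists named so far, estimated correlations ran from 0.07 (oxidative phosphorylation) to 0.627 (tricarboxylic acid cycle). All lay above the preset 0.01, so camera's p-values at the preset may be too small. CIS3, a cell wall mannoprotein gene on chromosome X (122265 to 122948, YJL158C), rose from 92.5 ± 17.7 TPM in T1 to 920.3 ± 65.7 TPM in T3 (SD, n = 2), a 9.93-fold change (log2 change 3.31, SE 0.12, limma adjusted p = 3.06e-10). CTS1, the chitinase gene that acts in cell separation on chromosome XII (708448 to 710136, YLR286C), fell from 160 ± 80 TPM to 12.8 ± 0.106 TPM, a log2 change of -3.44 (SE 0.23, limma adjusted p = 5.59e-08). The T1 replicates of CTS1 lay apart, at 103.4 TPM in A and 216.5 TPM in B.

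The other genes with the largest rises in T3 came from varied processes. BIO4, which encodes an enzyme of biotin synthesis (chromosome XIV, 733356 to 734069), went from 44.7 ± 2.96 to 448.9 ± 21.6 TPM and rose 9.85-fold (limma adjusted p = 2.82e-11). GPG1, whose product is proposed to act with the G protein Gpa2, rose 8.82-fold. PCL1, a G1 cyclin gene of the Pho85 kinase, rose 7.07-fold, and RNR1, which encodes the large subunit of ribonucleotide reductase, rose 6.77-fold. CLB2, a mitotic cyclin gene, went from 8.87 ± 2.73 to 59.7 ± 0.176 TPM and rose 6.27-fold. GPH1, the glycogen phosphorylase gene, rose 6.05-fold. MAL12, a maltase gene with a near-identical copy and therefore uncertain, rose 5.98-fold. Their limma adjusted p-values lay between 2.82e-11 for GPG1 and 2.45e-08 for CLB2.

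Among the largest falls, INO1, the inositol-3-phosphate synthase gene (chromosome X, 134332 to 135933), went from 61.1 ± 13.4 to 8.28 ± 0.828 TPM (log2 change -2.73, SE 0.15, limma adjusted p = 1.38e-08). CHA1, the gene of the catabolic serine and threonine deaminase, went from 100.2 ± 3.04 to 15.8 ± 0.853 TPM (log2 change -2.60, SE 0.11, limma adjusted p = 1.7e-09). AAD6, a putative aryl-alcohol dehydrogenase gene of a family with similar sequences and therefore uncertain, had a log2 change of -2.84. DSE1, DSE2, SCW11 and EGT2, which act in daughter cell separation, had log2 changes of -2.57, -2.60, -2.52 and -2.33. For these 4 genes too the T1 replicates lay apart, for example at 11.4 TPM in A and 32.7 TPM in B for EGT2.

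**Figure D1:**
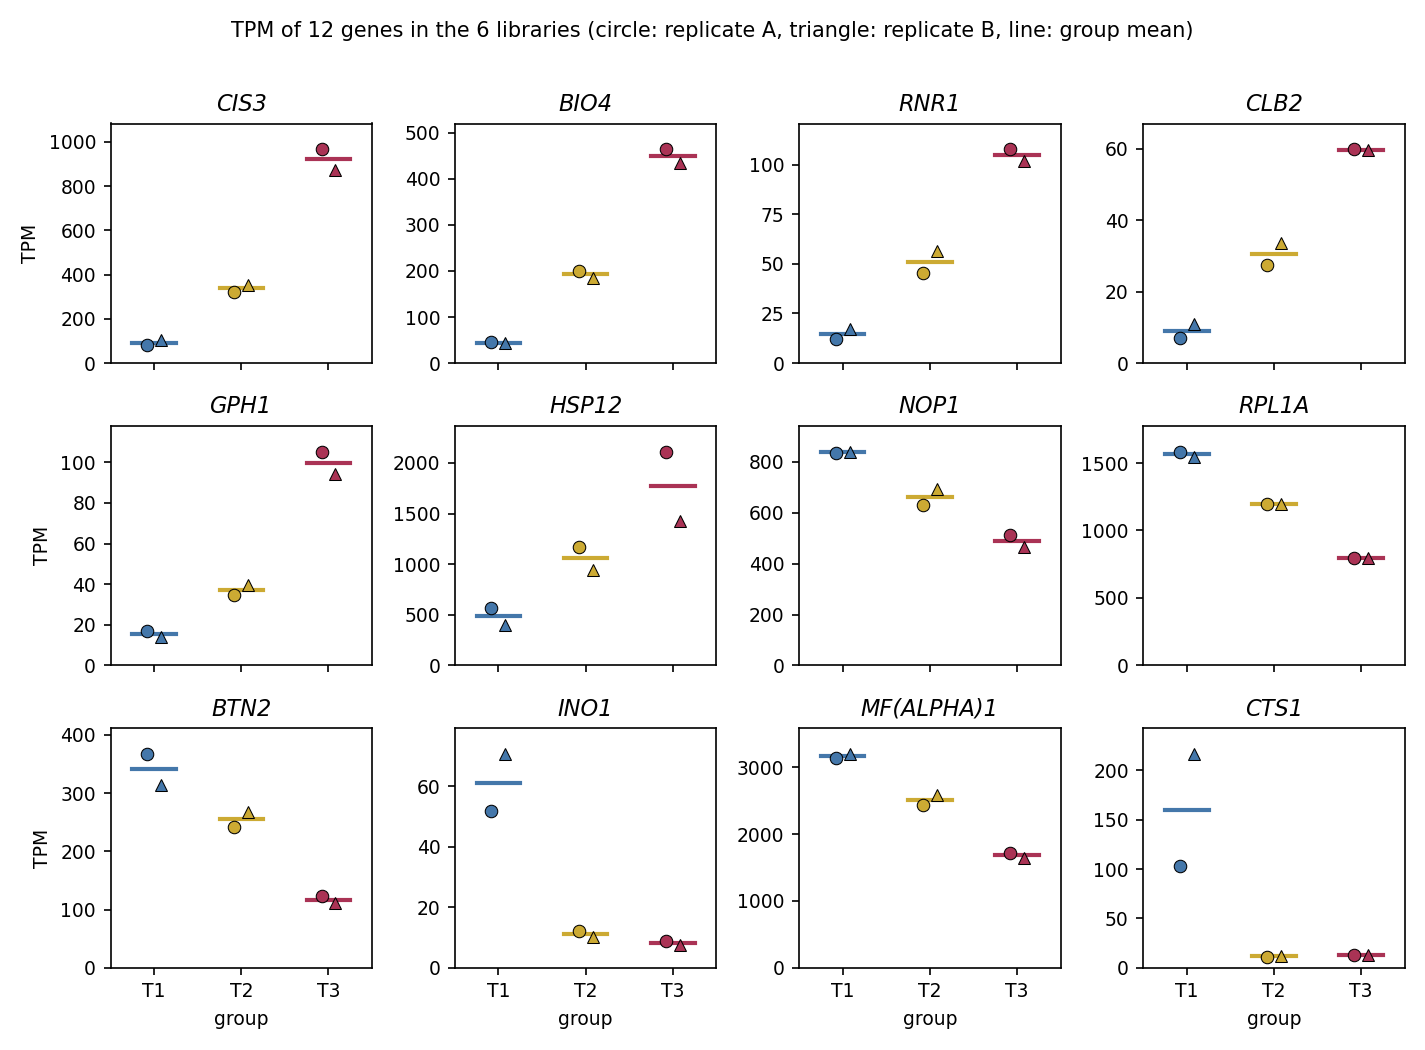
TPM of 12 genes in each library of T1, T2 and T3, on linear axes from 0. Circles are replicate A, triangles replicate B, and a horizontal line marks each group mean. CIS3 climbs from a mean of 92.5 TPM in T1 to 337.3 in T2 and 920.3 in T3, and CTS1 drops from 160 to 11.5 and 12.8.

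Of the 62 general stress genes, 51 rose and 3 fell (53 and 4 adjusted over the list alone; camera adjusted p = 7.29e-15). With an estimated correlation the adjusted p = 0.425. After quantile normalization 49 rose and 6 fell. HSP12, which encodes a small membrane-associated heat shock protein, went from 484 ± 112 to 1772 ± 483 TPM and rose 3.64-fold (limma adjusted p = 1.06e-06). DDR2 rose 4.26-fold, and CTT1, the cytosolic catalase gene, rose 2.04-fold. The members that fell were SSA4 and HSP42, which encode chaperones and are also in the chaperone list, and YGP1, named after its values were seen. The HSP42 call was lost without T1 replicate A (adjusted p = 0.0781), without T3 replicate B (0.221) and without the abundance trend (0.0577), with a range of 0.00228 to 0.221 over 18 settings. Of 21 trehalose and glycogen genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone; median log2 change 1.07; camera adjusted p = 5.32e-08, and adjusted p = 0.425 with an estimated correlation). They include TPS1, the trehalose-6-phosphate synthase gene (175.1 to 384.9 TPM), and GLC3, the glycogen branching enzyme gene (19.1 to 62.6 TPM). The stress list also holds TPS1, TPS2, TSL1, NTH1, GSY2, GLC3, GPH1 and PGM2, so the rises of these lists are not separate results.

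All 16 genes of the tricarboxylic acid cycle rose (16 adjusted over the list alone; median log2 change 0.82; camera adjusted p = 4.36e-08). With an estimated correlation the adjusted p = 0.425. ACO1, the aconitase gene, rose 1.73-fold and LSC2, a succinyl-CoA ligase gene, rose 2.35-fold. Of 36 nuclear genes of oxidative phosphorylation, 35 rose (35 adjusted over the list alone; median log2 change 0.60; camera adjusted p = 6.5e-11), with an adjusted p = 0.425 with an estimated correlation. ATP15, an ATP synthase gene at 3014 ± 190 TPM in T3, rose 1.98-fold, and COX13, a cytochrome c oxidase gene, rose 2.06-fold. Of 23 glyoxylate cycle and gluconeogenesis genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.425 with an estimated correlation). The call was lost among genes with a mean of at least 10 TPM (adjusted p = 0.0605, in a range of 0.000206 to 0.0605 over 18 settings). SFC1, a mitochondrial succinate-fumarate transporter gene, rose 2.72-fold, and ATO3, a putative ammonium transporter gene, had a log2 change of -0.77. Of 31 genes of the peroxisome and of fatty acid oxidation, 17 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 0.0124, and adjusted p = 0.703 with an estimated correlation). After quantile normalization 13 rose and 4 fell, and the call was lost without T1 replicate A (adjusted p = 0.0848, in a range of 0.00612 to 0.0848 over 18 settings). PEX11, a gene of peroxisome division, rose 2.15-fold.

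Of 36 autophagy genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone; median log2 change 0.37; camera adjusted p = 0.00228, and adjusted p = 0.425 with an estimated correlation). ATG8, the gene of the ubiquitin-like protein of autophagosome membranes, went from 48.8 ± 0.563 to 161.2 ± 3.42 TPM and rose 3.25-fold, and ATG39, a receptor gene of nuclear autophagy, rose 2.47-fold. ATG5 had a log2 change of -0.78 (limma adjusted p = 3.35e-05). Of 17 genes of vacuolar hydrolases and their inhibitors, 15 rose and 0 fell (15 adjusted over the list alone; median log2 change 0.55; camera adjusted p = 1.96e-05, and adjusted p = 0.425 with an estimated correlation). AMS1, the vacuolar alpha-mannosidase gene, rose 3.18-fold and PBI2, a proteinase B inhibitor gene, rose 2.22-fold. Of 38 proteasome genes, 22 rose and 0 fell (23 adjusted over the list alone; median log2 change 0.28; camera adjusted p = 0.0021, and adjusted p = 0.703 with an estimated correlation), among them UMP1, an assembly factor gene, by 1.59-fold. The proteasome count was 16 after rescaling by the median of ratios and 7 after quantile normalization, with 1 fall, and the list's call was lost without T1 replicate A (adjusted p = 0.18) and among genes of at least 500 nt (0.0748), in a range of 0.000748 to 0.18 over 18 settings.

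Of 135 ribosome biogenesis genes, 97 fell and 0 rose (108 adjusted over the list alone; median log2 change -0.40; camera adjusted p = 5.66e-22). With an estimated correlation the adjusted p = 0.425. NOP1, the fibrillarin gene, went from 837.6 ± 4.05 to 490.4 ± 32.9 TPM (log2 change -0.77, limma adjusted p = 6.22e-06), and MTR4, an RNA helicase gene of the nuclear exosome, had a log2 change of -1.09. Of 138 cytosolic ribosomal protein genes, 91 fell and 3 rose (95 and 3 adjusted over the list alone; median log2 change -0.28; camera adjusted p = 5.66e-22, and adjusted p = 0.425 with an estimated correlation). RPL1A went from 1566 ± 27.2 to 793.5 ± 1.09 TPM and RPL15B from 44.3 ± 0.664 to 72.9 ± 7.46 TPM, as examples of a fall and a rise. Many of these genes have a near-identical copy, so values of single members are uncertain. Their summed share of all TPM was 43.8% and 41.8% in the T1 libraries, 41.5% and 39.1% in T2, and 35.2% and 37.1% in T3. After quantile normalization 64 fell and 10 rose, and after rescaling by the median of ratios 96 fell and 1 rose.

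Of 20 genes of RNA polymerases I and III, 10 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.000252, and adjusted p = 0.425 with an estimated correlation), with RPC17 and RPA34 at log2 changes of -0.90 and -0.73. Of 12 RNA polymerase II genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00279, and adjusted p = 0.425 with an estimated correlation). Falls numbered 10 after quantile normalization, and the call was lost among genes of at least 500 nt (adjusted p = 0.0858, in a range of 0.00123 to 0.0858). RPB9 and RPB3 had log2 changes of -0.64 and -0.59. RPO21, the gene of the largest subunit, lay at 62.1 ± 4.67 and 56.3 ± 6.22 TPM and did not pass the test (limma adjusted p = 0.314), but it did after quantile normalization (0.0241) and after removal of the length trend (0.0248), in a range of 0.0241 to 0.881. Of 38 translation factor genes, 18 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 7.15e-06, and adjusted p = 0.564 with an estimated correlation), among them TIF4631, which encodes eIF4G, at a log2 change of -0.85. Of 75 mitochondrial ribosomal protein genes, 18 fell and 3 rose (17 and 3 adjusted over the list alone; camera adjusted p = 0.000106, and adjusted p = 0.564 with an estimated correlation). For these the count of falls was 32 after rescaling by the median of ratios and 41 after quantile normalization. MNP1 had a log2 change of -0.47 and YMR31 rose 2.05-fold; YMR31 is now counted with the 2-oxoglutarate dehydrogenase complex.

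Of 24 chaperone genes, 19 fell and 1 rose (20 and 1 adjusted over the list alone; median log2 change -0.54; camera adjusted p = 2e-09). With an estimated correlation the adjusted p = 0.425. BTN2, a gene of protein aggregate sorting, went from 340.6 ± 37.8 to 116.9 ± 8.39 TPM (log2 change -1.53, SE 0.10, limma adjusted p = 7.28e-08). APJ1, a Hsp40 gene, had a log2 change of -1.30. SSA4, a stress-induced Hsp70 gene, had a log2 change of -0.81, and SSA3, another gene of that family, rose 1.39-fold. Of 24 DNA damage response genes, 14 rose and 2 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.00917, and adjusted p = 0.564 with an estimated correlation), and the call was lost among genes of at least 500 nt (adjusted p = 0.114, in a range of 0.00396 to 0.114). DUN1, a checkpoint kinase gene that is also in the G1/S list, rose 3.02-fold, and YHB1, the flavohemoglobin gene, had a log2 change of -0.85.

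Of 52 genes expressed at the G1 to S transition, 39 rose and 0 fell (41 adjusted over the list alone; median log2 change 0.58; camera adjusted p = 3.03e-09, and adjusted p = 0.425 with an estimated correlation). They include PCL1 and RNR1, and WTM1, a transcriptional modulator gene that went from 106.1 ± 9.47 to 272.3 ± 21.2 TPM. Of 9 histone genes, 7 rose and 0 fell (7 adjusted over the list alone; median log2 change 0.75; camera adjusted p = 0.000904, and adjusted p = 0.425 with an estimated correlation). HHO1, the linker histone gene, rose 2.28-fold and HTA2 had a log2 change of 1.32; core histone copies are near-identical and uncertain. Of 33 G2/M genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.0401, and adjusted p = 0.747 with an estimated correlation). Beside CLB2, SPO12, a mitotic exit gene, rose 2.05-fold, and AMN1 fell from 21.2 and 39.4 TPM in the T1 libraries to 10.3 and 10.1 TPM in T3. After quantile normalization 9 rose and 3 fell. The G2/M call was lost without T1 replicate A (adjusted p = 0.221), without T3 replicate A (0.058), without T3 replicate B (0.0617) and among genes of at least 500 nt (0.0733), in a range of 0.0107 to 0.221.

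Of 25 genes of the M to G1 transition, 12 fell and 6 rose (12 and 6 adjusted over the list alone), with a median log2 change of -0.10 and a mean of -0.49 (camera adjusted p = 0.0417, and adjusted p = 0.747 with an estimated correlation). The call was lost after rescaling by the median of ratios (adjusted p = 0.162) and after quantile normalization (0.248), among other settings, in a range of 3.65e-07 to 0.248. The falls include CTS1 and DSE2, and the rises PIR3 and PIR1, cell wall protein genes that rose 2.56-fold and 2.47-fold. Of 45 cell wall genes, 23 rose and 4 fell (24 and 4 adjusted over the list alone; camera adjusted p = 0.000513, and adjusted p = 0.651 with an estimated correlation). CWP2, a wall mannoprotein gene, went from 2958 ± 210 to 8752 ± 19.4 TPM and YPS3, an aspartic protease gene, rose 3.60-fold. UTR2 and TIP1 had log2 changes of -0.65 and -0.55.

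Over the 6 libraries, the alpha-cell genes MF(ALPHA)1, MF(ALPHA)2, AFB1, STE3 and SAG1 lay at 19.55 TPM or more. The a-cell genes STE2, MFA1, MFA2, STE6, BAR1, ASG7 and AGA2 lay at 0.77 to 11.25 TPM. The MATALPHA and HMLALPHA genes, which have identical stretches and are uncertain, lay at 0.22 to 17.9 TPM. MF(ALPHA)1, the alpha-factor gene, lay at 3168 ± 44.7 TPM in T1, 2512 ± 107 in T2 and 1681 ± 46 in T3. Of 7 alpha-specific genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00279, and adjusted p = 0.425 with an estimated correlation), and the call was lost among genes of at least 500 nt (adjusted p = 0.204, in a range of 0.000748 to 0.204). The median log2 change was -0.797 over all 7 and -0.356 over the members of at least 500 nt. MF(ALPHA)1 had a log2 change of -0.91, SAG1, an agglutinin gene, of -1.07, and MATALPHA2, the repressor gene of the mating type locus, rose 2.13-fold. Of 30 pheromone response genes, 6 rose and 2 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.71), with a median log2 change of -0.006 and a mean of 0.062; 3 rose and 5 fell after quantile normalization. AFR1 rose 1.64-fold and SST2 had a log2 change of -0.71. Of 48 sporulation and meiosis genes, markers of diploid cells, 20 rose and 0 fell (20 adjusted over the list alone; camera adjusted p = 0.0489, and adjusted p = 0.425 with an estimated correlation). The sporulation call was lost without either T1 library (adjusted p = 0.133 without A and 0.411 without B), either T2 library (0.0583 and 0.0558) and T3 replicate B (0.182), and after quantile normalization (0.0777), among other settings, in a range of 0.00744 to 0.411.

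The remaining lists did not pass camera in T3 against T1, and each had an adjusted p of 0.747 or 0.872 with an estimated correlation. Of 71 amino acid synthesis genes, 33 rose and 5 fell (33 and 5 adjusted over the list alone; camera adjusted p = 0.0907), but 20 rose and 16 fell after quantile normalization. The list passed without T1 replicate B (adjusted p = 0.0447) and without T3 replicate B (0.0373), in a range of 0.0373 to 0.697. LYS1, a lysine synthesis gene, rose 2.33-fold and ARG8 had a log2 change of -0.67. Of 29 genes under nitrogen catabolite repression, 13 rose and 7 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.559), with DAL80, a GATA repressor gene, rising 3.42-fold and AGP1, an amino acid permease gene, at a log2 change of -0.72. Of 28 iron starvation genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.146), with HMX1, the heme oxygenase gene, rising 2.17-fold. After quantile normalization 12 rose and 6 fell. The iron list passed without T3 replicate B (adjusted p = 0.0405, in a range of 0.0405 to 0.377). Of 21 phosphate starvation genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.556), but 6 and 7 after quantile normalization, with PHM8 rising 2.15-fold.

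Among the lists of carbon and lipid metabolism, 5 of 17 genes of glycolysis and fermentation rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.559), with a median log2 change of 0.047 that turned to -0.035 after rescaling by the median of ratios. TDH1 rose 2.95-fold and PDC5 had a log2 change of -0.70. Of 18 hexose transporter genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.613), with HXT4 rising 2.17-fold and HXT2 and HXT1 at log2 changes of -1.29 and -0.96. Of 32 ergosterol and fatty acid genes, 15 rose and 5 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.458), but 7 and 8 after quantile normalization, with ERG10 rising 1.71-fold and OLE1, the fatty acid desaturase gene, at a log2 change of -0.64. Of 26 methionine and sulfate genes, 8 rose and 8 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.451), but 5 and 9 after quantile normalization. Their median log2 change was 0.067 although camera's direction was down, and it turned to -0.068 after quantile normalization and -0.012 after rescaling. MET28 rose 2.53-fold and SAM2, an S-adenosylmethionine synthetase gene, had a log2 change of -1.22. Of 41 nucleotide synthesis genes, 10 rose and 12 fell (10 and 12 adjusted over the list alone; camera adjusted p = 0.244), but 9 and 19 after quantile normalization, with a median of 0.022 that turned to -0.06 after rescaling and -0.162 after quantile normalization. IMD2 rose 2.00-fold and URA3 had a log2 change of -0.94.

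**Figure D2:**
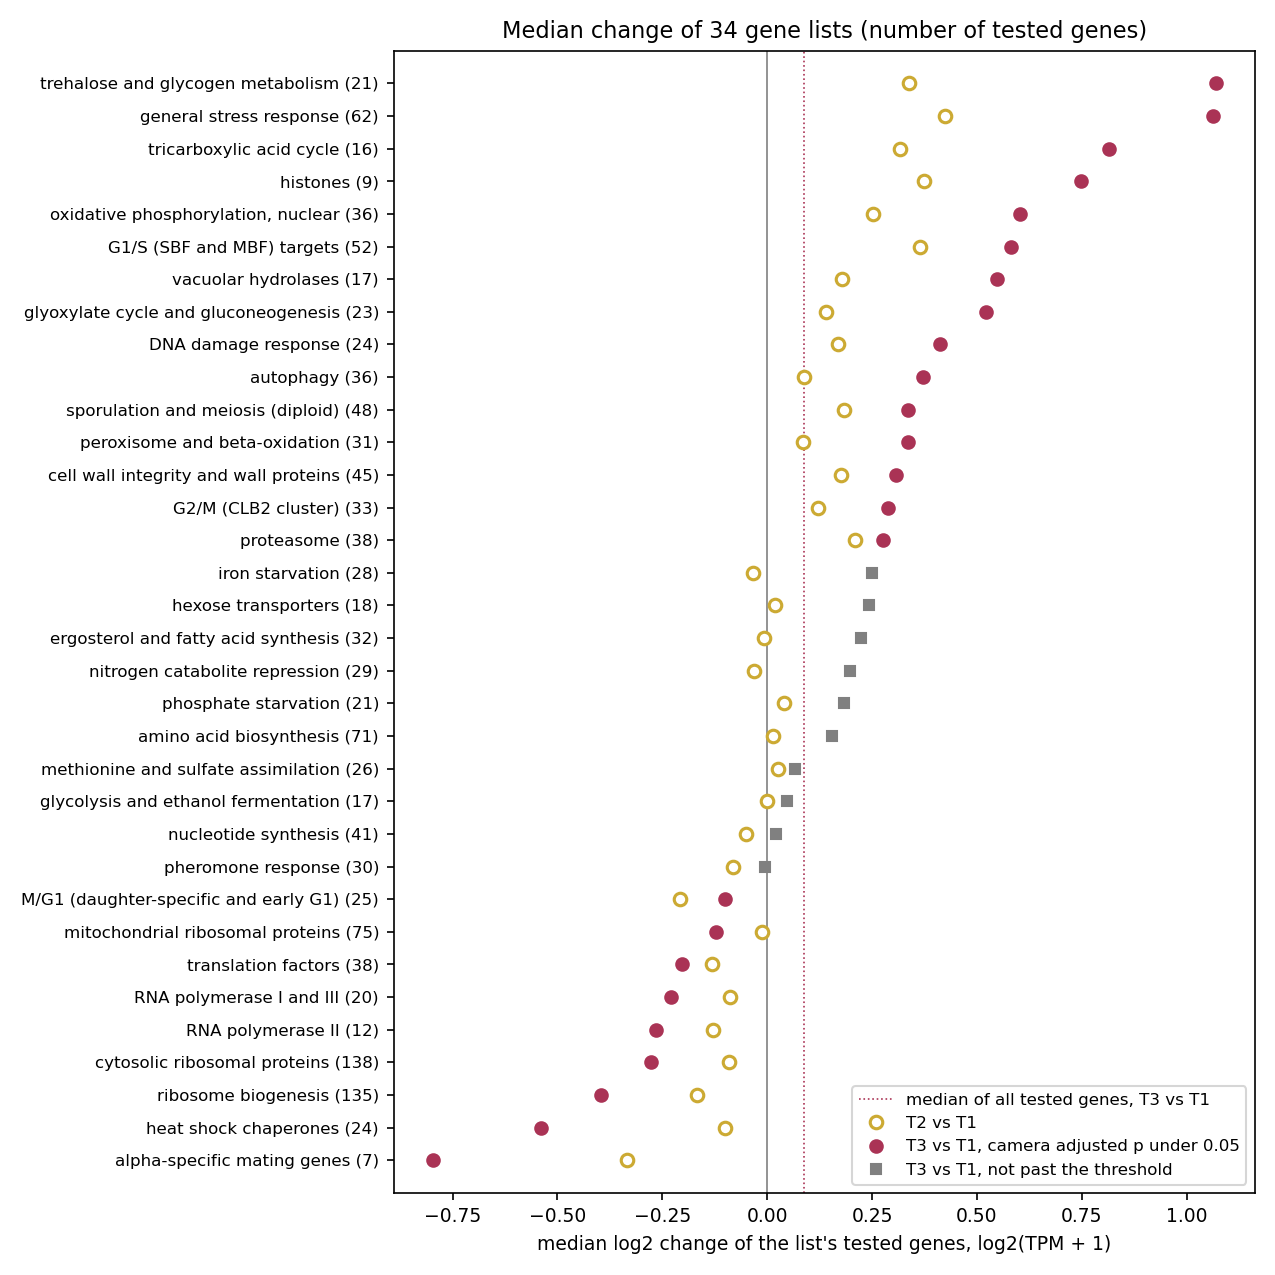
Median log2(TPM + 1) change of the tested members of 34 gene lists in T3 against T1 (filled where camera passed the threshold, grey squares where it did not) and in T2 against T1 (open circles), with a dotted line at the median of all tested genes, 0.088. Trehalose and glycogen genes lie at 1.07 and chaperone genes at -0.54 in T3 against T1.

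Among the genes taken by name, CLN1, a G1 cyclin gene, went from 48.3 ± 4.26 to 74.8 ± 0.622 TPM and rose 1.54-fold (limma adjusted p = 0.000277). CLN2, its paralog, lay at 47.6 ± 1.41 and 58.1 ± 1.76 TPM (adjusted p = 0.028), and its call was lost after rescaling by the median of ratios (0.0521), after quantile normalization (0.102) and when any 1 of the T1 or T3 libraries was left out (0.0525 and 0.125 without T1 replicates A and B, 0.0775 and 0.15 without T3 replicates A and B), in a range of 0.0105 to 0.15 over 18 settings. SIC1, an inhibitor gene of B-type cyclin kinases, rose 1.66-fold. CLN3, an upstream G1 cyclin gene, had a log2 change of 0.23 (adjusted p = 0.155) and SWI4, a G1/S activator gene, of 0.26 (adjusted p = 0.079, and 0.0129 with voom on the recovered fragments and 0.0411 with the length trend removed, in a range of 0.0129 to 0.378). WHI5, a repressor gene of G1/S transcription, had a log2 change of -0.28 (adjusted p = 0.2) that became -0.54 without T3 replicate A (adjusted p = 0.0369) and -0.03 without T3 replicate B (0.922). GCN4, the activator gene of amino acid synthesis, rose 1.40-fold. PMA1, the plasma membrane proton pump gene, had a log2 change of -0.36 (limma adjusted p = 0.00638). MSN4, a stress activator gene, rose 1.30-fold, a call that was lost without T3 replicate A (0.0842, in a range of 0.00094 to 0.0842), and MSN2 lay at 21.3 ± 1.5 and 21.8 ± 2.49 TPM (adjusted p = 0.863). SFP1, an activator gene of ribosomal genes, had a log2 change of -0.28 (adjusted p = 0.0506) and passed in 9 of 18 settings, among them both rescalings (0.0054 by the median of ratios and 0.00297 by quantiles) and voom (0.00571), in a range of 0.00277 to 0.29. ACT1 had a log2 change of 0.16 (adjusted p = 0.0954, and 0.0039 after quantile normalization, in a range of 0.0039 to 0.443) and TDH3 of 0.08 (adjusted p = 0.345).

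In total, limma called 2901 of 6046 genes in T3 against T1 (48%), 1877 higher and 1024 lower, and 340 and 61 of them changed by at least 1 on the log2 scale. Libraries of T1 and T3 did not overlap for 4538 genes, where chance gives 33.3% of genes. Higher calls made up 64.7% as deposited, 52.5% after rescaling by the median of ratios (1651 higher and 1491 lower), 45.2% after quantile normalization (1419 and 1722) and 50.1% with the length trend removed (1729 and 1722). Quantile normalization moved the median log2 change of all genes by -0.126, from 0.088 to -0.038, and camera compares each list with the other genes whichever the baseline. The median of the stress list was 0.936 after quantile normalization and that of the ribosome biogenesis list -0.529. Of the lists, camera called 24, 15 up and 9 down. With an estimated correlation it called 0 (lowest adjusted p = 0.425), and fry called 21. Of the lists that camera called, fry missed translation factors, mitochondrial ribosomal proteins and M to G1 genes (fry adjusted p = 0.0696, 0.107 and 0.586). Lists tested with fry are not compared with other genes.

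**Figure D3:**
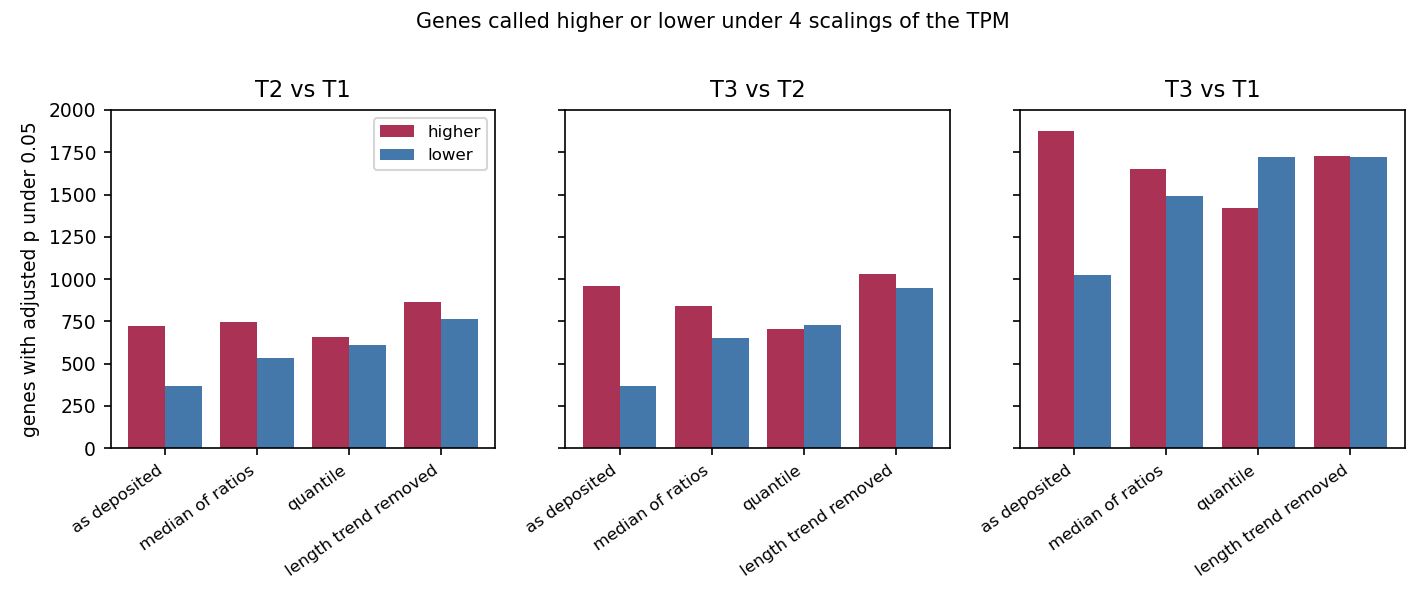
Number of genes called higher and lower by limma in each pair of groups under 4 scalings of the TPM values (bars from 0). In T3 against T1 the higher and lower calls number 1877 and 1024 as deposited and 1419 and 1722 after quantile normalization.

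T2 was compared with T1 to describe the step between these adjacent labels. BIO4 rose 4.24-fold, from 44.7 ± 2.96 to 192.5 ± 9.88 TPM (SD, n = 2; limma adjusted p = 2.75e-08), and GPG1 and CIS3 both rose 3.65-fold. RNR1 and CLB2 rose 3.31-fold and 3.23-fold. The largest falls were those of the cell separation genes. CTS1 went to 11.5 ± 0.626 TPM in T2 (log2 change -3.59, SE 0.23, limma adjusted p = 3.16e-07), and DSE2, DSE1, EGT2 and SCW11 had log2 changes of -2.86, -2.77, -2.55 and -2.47.

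Of the 25 M to G1 genes, 11 fell and 1 rose in T2 (11 and 4 adjusted over the list alone; camera adjusted p = 8.91e-05, and adjusted p = 0.803 with an estimated correlation). Of 52 G1/S genes, 26 rose and 1 fell (30 and 1 adjusted over the list alone; median log2 change 0.36; camera adjusted p = 6.01e-11, and adjusted p = 0.717 with an estimated correlation), and 5 of 9 histone genes rose (5 adjusted over the list alone; camera adjusted p = 0.00409, and adjusted p = 0.717 with an estimated correlation). Of 62 stress genes, 35 rose and 0 fell (38 and 1 adjusted over the list alone; median log2 change 0.42; camera adjusted p = 8.13e-13, and adjusted p = 0.717 with an estimated correlation), with HSP12 at 1057 ± 160 TPM. Respiration genes rose in part, with 17 of 36 genes of oxidative phosphorylation (22 adjusted over the list alone; camera adjusted p = 2.03e-07, and adjusted p = 0.717 with an estimated correlation) and 9 of 16 of the tricarboxylic acid cycle (9 adjusted over the list alone; camera adjusted p = 8.91e-05, and adjusted p = 0.803 with an estimated correlation). These counts were 12 and 9 after rescaling by the median of ratios and 10 and 6 after quantile normalization. Of 38 proteasome genes, 10 rose (14 adjusted over the list alone; camera adjusted p = 0.00049, and adjusted p = 0.803 with an estimated correlation), against 15 after rescaling by the median of ratios and 6 after quantile normalization. The proteasome call was lost without T1 replicate A (adjusted p = 0.0788, in a range of 0.000101 to 0.0788). Of 135 ribosome biogenesis genes, 25 fell (25 adjusted over the list alone; camera adjusted p = 3.69e-10, and adjusted p = 0.803 with an estimated correlation), and 47 fell after rescaling by the median of ratios and 55 after quantile normalization. Of 138 cytosolic ribosomal protein genes, 23 fell and 2 rose (23 and 3 adjusted over the list alone; camera adjusted p = 8.88e-07, and adjusted p = 0.803 with an estimated correlation), against 13 and 7 after quantile normalization, and that call was lost without T1 replicate A (adjusted p = 0.0582, in a range of 1.47e-15 to 0.0582). The chaperone list did not pass (camera adjusted p = 0.131), with 5 falls and 3 rises (6 and 4 adjusted over the list alone), among them SSA4 from 247.6 ± 42.1 to 365.9 ± 40.2 TPM.

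Limma called 1091 genes in T2 against T1, 722 higher and 369 lower, of which 52 and 37 changed by at least 1 on the log2 scale. Higher calls made up 66.2% as deposited, 58.1% after rescaling by the median of ratios (744 and 536), 51.8% after quantile normalization (660 and 613) and 53% with the length trend removed (863 and 764). Camera called 18 lists, 11 up and 7 down, against 0 with an estimated correlation (lowest adjusted p = 0.717) and 3 with fry. Those 3 were the oxidative phosphorylation, histone and sporulation lists (fry adjusted p = 0.0244 each). Fry missed the other lists, among them stress, G1/S, ribosome biogenesis and proteasome (fry adjusted p = 0.128, 0.0656, 0.233 and 0.195). The gene count was 650 without T2 replicate A and 705 without T2 replicate B.

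T3 was compared with T2 to describe the step between the other adjacent labels. MAL12, uncertain because of its near-identical copy, rose 3.48-fold, from 5.7 ± 0.264 to 22.4 ± 2.71 TPM (SD, n = 2; limma adjusted p = 7.6e-06). PUT4, the proline permease gene, rose 2.81-fold, SRX1, the sulfiredoxin gene, 2.75-fold, CIS3 2.72-fold and GPH1 2.65-fold. CHA1 had a log2 change of -1.67 (SE 0.11, limma adjusted p = 2.91e-06), and SSA4 went from 365.9 ± 40.2 to 139.9 ± 11.4 TPM (log2 change -1.38, SE 0.12, limma adjusted p = 1.12e-05). BSC1 and BTN2 had log2 changes of -1.22 and -1.12. The valine tRNA gene tV(UAC)D had a log2 change of -0.94 (limma adjusted p = 0.0234), which was lost without T2 replicate A (-0.61, adjusted p = 0.216), without T3 replicate A (0.0521), after rescaling by the median of ratios (0.0644), after quantile normalization (0.0509), without the abundance trend (0.0721) and with no abundance filter (0.0562), in a range of 3.76e-07 to 0.216 over 13 settings.

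Of 24 chaperone genes, 19 fell and 0 rose in T3 against T2 (20 and 0 adjusted over the list alone; median log2 change -0.48; camera adjusted p = 1.75e-16, and adjusted p = 0.376 with an estimated correlation). Of 62 stress genes, 48 rose and 4 fell (49 and 4 adjusted over the list alone; median log2 change 0.67; camera adjusted p = 1.76e-16, and adjusted p = 0.376 with an estimated correlation). All 16 genes of the tricarboxylic acid cycle (16 adjusted over the list alone; camera adjusted p = 1.09e-09, and adjusted p = 0.376 with an estimated correlation) and 18 of 21 trehalose and glycogen genes rose (18 adjusted over the list alone; camera adjusted p = 5.78e-11, and adjusted p = 0.376 with an estimated correlation). Of 138 cytosolic ribosomal protein genes, 60 fell and 0 rose (72 and 1 adjusted over the list alone; camera adjusted p = 1e-28, and adjusted p = 0.376 with an estimated correlation), against 29 and 1 after quantile normalization. Of 135 ribosome biogenesis genes, 38 fell (43 adjusted over the list alone; camera adjusted p = 1.66e-21, and adjusted p = 0.386 with an estimated correlation), against 82 after rescaling by the median of ratios and 86 after quantile normalization. Of 71 amino acid synthesis genes, 28 rose and 4 fell (37 and 5 adjusted over the list alone; camera adjusted p = 0.00208, and adjusted p = 0.77 with an estimated correlation), against 16 and 6 after quantile normalization. Of 29 genes under nitrogen catabolite repression, 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.0046, and adjusted p = 0.589 with an estimated correlation), against 8 and 3 after quantile normalization. Proteasome and M to G1 genes did not pass (camera adjusted p = 0.424 and 0.166), with 1 and 7 rises (0 and 8 adjusted over the list alone). The M to G1 list passed without either T1 library (adjusted p = 0.027 without A and 0.0293 without B) and among genes of at least 500 nt (0.0255), in a range of 0.0255 to 0.341.

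Limma called 1325 genes in T3 against T2, 957 higher and 368 lower, of which 66 and 6 changed by at least 1 on the log2 scale. Higher calls made up 72.2% as deposited, 56.5% after rescaling by the median of ratios (844 and 651), 49.2% after quantile normalization (706 and 730) and 52% with the length trend removed (1030 and 949). Camera called 24 lists, 16 up and 8 down, against 0 with an estimated correlation (lowest adjusted p = 0.376) and 15 with fry. Of the lists described above that camera called, fry missed ribosome biogenesis, amino acid synthesis and nitrogen catabolite repression (fry adjusted p = 0.0773, 0.188 and 0.052). The gene count was 641 without T3 replicate A and 735 without T2 replicate A.

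For CIS3, BIO4, GPG1 and RNR1 the T2 mean lay between those of T1 and T3, as it did for 1711 of the 1877 genes called higher in T3 against T1 (91.2%) and for 906 of the 1024 called lower (88.5%). These genes were picked for a difference between T1 and T3, which by itself raises these shares. Over all tested genes the adjacent steps had the same sign for 63.8%, against 33.3% in simulated unchanged groups. A test over all groups called 2639 genes. Both comparisons with T1 called 692 genes higher and 318 lower, where independent lists would share 224.1 and 62.5, and simulated unchanged groups against the same T1 libraries shared 0.04 and 0.03. Across genes, which are not independent replicates, the log2 changes of T2 and of T3 against T1 correlated at 0.834, with 0.5 for simulated unchanged groups. Their covariance was 0.141 against 0.0093. The changes of the 2 adjacent steps correlated at 0.359, against -0.499 for unchanged groups, with a covariance of 0.0358 against -0.0093. The 2 T1 libraries are too few to split, so part of the excess of genes called in both comparisons may come from these shared libraries. For the adjacent steps the shared T2 libraries lower the correlation, as the simulated value shows.

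The test of the difference between the T2 to T3 step and the T1 to T2 step called 65 genes, 46 positive and 19 negative. Cell separation genes led the positive side and SSA4 the negative side. Of the 25 M to G1 genes, 9 differed, all positive, and of the 24 chaperone genes, 4 differed, all negative (SSA4, and AHA1, CPR6 and HSP10, named after their values were seen). The count was 10 after quantile normalization and 21 after rescaling by the median of ratios, and 18 without T2 replicate A. The spacing of the groups is not stated, so the steps are compared as sampled.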

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

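The tests of single T1 and T2 libraries were chosen after the result was seen, and the T1 test replaced a count of genes still called (65 of 65 without either library), in which limma's prior took over the spread. Between the T1 to T2 step and the T2 to T3 step, limma's test of the difference itself called 65 genes, and 45 of them differed by at least 1 on the log2 scale. The largest positive values, the T2 to T3 change minus the T1 to T2 change on the log2 scale, were 3.74 for CTS1, 3.12 for DSE2, 2.97 for DSE1 and 2.82 for DSE4 (limma adjusted p = 0.000378, 0.0012, 0.00191 and 0.0154). These 4 genes act in the separation of daughter cells, and CTS1 fell by 3.59 in the first step with a change of 0.15 in the next. The most negative values were -1.95 for SSA4, -1.59 for YJR154W, -1.41 for AAD10 and -1.36 for YFR012W-A (limma adjusted p = 0.000378, 0.00126, 0.00201 and 0.0262). SSA4, a Hsp70 gene, changed by 0.57 and then by -1.38, and YJR154W by 1.43 and then -0.16. AAD10 belongs to a family of similar sequences, so its value is uncertain. Of the 8, the calls of DSE4 and YFR012W-A were lost without T2 replicate A (adjusted p = 0.13 and 0.291). After quantile normalization those of CTS1, DSE2, DSE1, DSE4, AAD10 and YFR012W-A were lost (adjusted p = 0.054, 0.0562, 0.0562, 0.124, 0.0573 and 0.144), at sizes of 3.65, 3.03, 2.87, 2.69, -1.44 and -1.42. The sizes stayed close to those before, while the SE went from 0.39 to 0.48, 0.37 to 0.44, 0.39 to 0.42, 0.49 to 0.58, 0.19 to 0.22 and 0.26 to 0.33, and limma's prior degrees of freedom from 10.7 to 4.3. Other settings ended calls too: DSE1 after rescaling by the median of ratios (0.0574) and without the abundance trend (0.0516), DSE2 without that trend (0.0515), DSE4 and YFR012W-A with no abundance filter (0.0958 and 0.117), after that rescaling (0.116 and 0.136), without the trend (0.144 and 0.158) and with voom (0.0548 and 0.142), and DSE4 with the length trend removed (0.0627). The highest adjusted p-values over all settings were 0.054, 0.0562, 0.0574, 0.144, 0.0573 and 0.291 for CTS1, DSE2, DSE1, DSE4, AAD10 and YFR012W-A. SSA4 and YJR154W stayed under the threshold in each of 18 settings, with adjusted p-values up to 0.0476 for both.

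A technical source in a single T1 or T2 library stays open for the 65 genes. The T1 replicates lay apart for CTS1 (103.4 and 216.5 TPM), whose difference was 4.27 without replicate A and 3.21 without B. The median size of the differences was 100.7% or more of its value without either T1 library and 98% or more without either T2 library, but these genes were picked for differences large against the spread of the replicates, so this decides nothing. Without T2 replicate A 16 of the 65 genes passed, and without B 29. A change of the cells between the groups that is not proportional from step to step may remain as well, but the labels give no spacing of the groups and no biological explanation was tested.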

How the results depend on the processing

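The alternatives were planned, except voom on recovered fragments, removal of the length trend and genes of at least 500 nt, which were chosen after the data were seen. No named gene that passed the threshold reversed its direction in them, nor did any list that camera called at the preset correlation in T3 against T1, T2 against T1 or T3 against T2, over 17 or 18 settings each. T3 against T1 called 2204 to 2910 genes without single libraries, and any difference among groups 1961 to 2665. T2 against T1 ranged from 650 (without T2 replicate A; 705 without T2 replicate B) to 1097, and T3 against T2 from 641 (without T3 replicate A; 735 without T2 replicate A) to 1687. Without a library the lone one of its group is assumed to vary like the others, and without either T1 library, as among genes of at least 500 nt, limma's prior took over the spread of single genes entirely, so p-values of those fits are too small. A change of at least 1 on the log2 scale left 401, 89 and 72 genes in T3 against T1, T2 against T1 and T3 against T2, and 416 for any difference.

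The count of 65 genes whose steps differ was not stable. It was 17 with no abundance filter, 113 at 10 TPM or more, 21 after rescaling by the median of ratios, 10 after quantile normalization, 124 for protein-coding genes alone, 15 without the abundance trend and 200 among genes of at least 500 nt. Single libraries left out gave 18 (T2 replicate A) to 254 (T1 replicate A), with 43 without T2 replicate B and 224 without T1 replicate B. Limma's prior degrees of freedom moved with many of these counts. They were 4.3 after either rescaling, 5 without the abundance trend, 6.3 with no filter and 10.7 in the main fit. For protein-coding genes alone they were 21.5, and at 10 TPM or more 22.5. Without either T1 library and among genes of at least 500 nt, the prior took over the spread. With the length trend removed, 72 genes differed at 4.9, so the prior does not account for every count. The cause was not tested further. The A minus B differences in T1 and T2, T1 and T3, and T2 and T3 correlated at 0.132, -0.058 and -0.15. Those differences also followed gene length, at -0.35 in T1, -0.435 in T2 and 0.317 in T3. The correlations therefore cannot show whether libraries of the same letter belong together, and the labels do not say. With a replicate block, 43 genes differed between steps, and 2819, 971 and 1235 genes were called in T3 against T1, T2 against T1 and T3 against T2.

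With an estimated inter-gene correlation, camera called 0, 0 and 0 lists in T3 against T1, T2 against T1 and T3 against T2. The preset correlation called 24, 18 and 24, and fry 21, 3 and 15. Camera with an estimated correlation rests on 3 residual degrees of freedom and has little power here. In T3 against T1 the histone list went from a camera adjusted p = 0.000904 to 0.425. Its estimated correlation was -0.023, below the preset 0.01, so that loss does not come from correlation among its members. Many other lists had higher estimates, such as 0.336 for stress, 0.484 for ribosome biogenesis, 0.529 for chaperones and 0.627 for the tricarboxylic acid cycle. For these, correlation among members and the few degrees of freedom cannot be told apart as the source of the loss. Of 192 named values, 170 kept their side of the threshold after quantile normalization, 17 lost the call and 5 gained it. Depth limits little here: the median open reading frame held at least 1104 fragments in each library.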

Other observations

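The biotin, vitamin B6 and phospholipid gene groups and the test of the split of higher and lower calls were chosen after the values were seen. All 5 genes of biotin synthesis and uptake rose in T3 against T1, by a median of 2.96-fold. BIO2, the biotin synthase gene, went from 205.4 ± 9.32 TPM in T1 to 525.8 ± 16.5 in T2 and 610.9 ± 9.94 in T3 (SD, n = 2), and BIO3 rose 3.00-fold in T3 against T1. BIO5 and VHT1 are also in the iron starvation list. In T2 against T1 all 5 rose as well, and in T3 against T2 BIO4 alone passed. SNZ1 and SNO1, genes of vitamin B6 synthesis with similar copies, rose 4.22-fold and 3.64-fold in T3 against T1.

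Of 12 genes of phospholipid synthesis and uptake that respond to inositol and choline, 10 fell and 0 rose in T3 against T1, with a median log2 change of -0.911, and 12 fell after either rescaling. The largest of these falls was that of INO1. OPI3, a phospholipid methyltransferase gene, went from 903.6 ± 26 to 432.1 ± 18 TPM (log2 change -1.06), and CHO1, the phosphatidylserine synthase gene, from 363.2 ± 31.9 to 193.2 ± 5.03 TPM (log2 change -0.90). In T2 against T1 7 of the 12 fell, and in T3 against T2 8 fell.

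For the genes changed in T3 against T1, technical explanations were set against the group difference itself. The rule set beforehand for a shift of the TPM scale used the median log2 change of all genes and the share of higher calls. The median of 0.088 fell short of its threshold, while the share passed, moving by 12.2 points. Without single libraries the median ranged from 0.058 to 0.117, on both sides of its threshold. A count of kept calls, not set beforehand, was then used in place of this rule. After rescaling by the median of ratios, 2660 of the 2901 genes were still called in the same direction (91.7%). A shift of the TPM scale is therefore unlikely as the whole source. The 20 most abundant genes held 17.8% of TPM in T1 and 17.2% in T3, a difference of -0.59 points. Gene length correlated with the log2 change at -0.069 across 5919 genes. Neither the share of those 20 genes nor a steady trend with length could account for the calls as a set. The 20 genes do not cover all ribosomal protein genes, whose share was 43.8% and 41.8% in the T1 libraries and 35.2% and 37.1% in T3. The excess of higher over lower calls stays open: its share of 64.7% became 52.5%, but centring the genes nearly fixes that split and TPM carries no absolute scale. At a fixed TPM total, the lower ribosomal protein share goes with a higher summed share of the other genes. How much of the excess this gives was not tested. A biological difference between the groups may remain as a hypothesis for the changed genes.

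A hypothesis of weaker silencing near chromosome ends was tested on the 186 genes within 20 kb of an end, of which 65 rose and 20 fell in T3 against T1. Their median log2 change was 0.22, and 1307 of 10000 random lists matched on T1 abundance had a median as high, with 95% of them between 0.1 and 0.254. Resampling the genes gave 0.113 to 0.315, so a difference could be neither shown nor excluded. Which group had the larger cells is not stated.

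A second hypothesis was that the stress genes may have risen with progress through the cell cycle. Of the G1/S, histone and G2/M lists, 75%, 77.8% and 42.4% of the members were called in T3 against T1, beside 48% of all tested genes. The lists did not all pass the share of 50% set beforehand, nor all miss it. That share lay close to the one over all genes, and calls of these lists cannot show what moved the stress genes. The hypothesis therefore stays open.

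No chromosome's median log2 change in T3 against T1 differed from that of the others by more than 0.109 (chromosome VI). Of 76 snoRNA genes 17 rose and 17 fell, and of 146 tRNA genes 42 rose and 26 fell, in libraries where both kinds together made up 0.288 to 0.364% of TPM. Across genes, length correlated with the A minus B difference of replicates at -0.35 in T1, -0.435 in T2 and 0.317 in T3.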
